A study of Gallus gallus with 8 samples.

How the data were processed

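Expression was measured by droplet single-cell RNA sequencing of embryonic chick spinal cord in 8 libraries of 5 groups. These were brachial cord at day 5 and day 7 (1 library each), brachial and lumbar cord at day 10 (2 each), and day 10 brachial cord of embryos with induced polydactyly (2). Per the labels, cells were freed with papain, samples above 80% viability were kept, and a 3 prime kit of version 3.1 with dual indices was used. The protocol speaks of dissected lateral motor columns, while the sample source reads spinal cord. The cell classes below cover the whole cord, from roof plate to floor plate.

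The values used are raw UMI counts per gene and cell barcode, deposited without normalization, from Cell Ranger. Version 3.1.0 and genome GRCg6a are given per the submitters' processing notes. Per the file headers, version 5.0.1 was used for the day 5 and day 7 libraries and 3.1.0 for the day 10 libraries, so age and pipeline version cannot be told apart. Barcodes had been called as cells before deposit, with a smallest total of 500 UMIs or just above. Each file held 16828 features, 12511 of them with a symbol, and 63 symbols are shared by several identifiers. Features without a symbol were tested under their identifier. A gene table of assembly GRCg7b was used only to place symbols on the Z and W chromosomes. It held 11609 of the 12511 symbols, or 12002 with synonyms, and put 544 genes on Z and 2 on W.

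Of 44328 barcodes, 36220 had at least 1000 UMIs, at least 500 genes and at most 15% mitochondrial UMIs. The share that passed was 90.2% at day 5, 84.2% at day 7, 87.9 and 79.1% in brachial, 75 and 76.7% in lumbar and 84.8 and 75.9% in polydactyl libraries. Median mitochondrial shares were 5.32, 4.89, 4.85, 5.74, 8.7, 8.01, 6.54 and 6.75% in the same order. Doublets were scored with Scrublet per library, and the highest scores were left out at 0.8% per 1000 barcodes, 1816 barcodes in all. The cells used numbered 5520, 6916, 2647, 5540, 2412, 4360, 2708 and 4301. Their median UMIs were 12480.5, 6753.5, 12998, 9503, 9782.5, 8447.5, 11840 and 9567. At the library sums, 1 UMI in the least deep library is 0.0408 CPM. Counts were 0 in a group where a fold is printed as a lower bound, with a floor of 3 counts over the group.

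Cells of all libraries were clustered together without integration. Counts were scaled to 10000 per cell, logged, limited to 2000 variable genes without HOX, Z, W, mitochondrial or haemoglobin genes, and reduced to 30 principal components of values held to 10. Leiden clustering used 15 neighbours and resolution 1 (alternative 2), with seed 1, and gave 45 clusters (65). Marker lists of 20 cell types were fixed before the data were examined. A cluster took the type with the highest score where at least 3 markers stood at least 1.5-fold above the other cells (pseudocount 10 CPM) and were seen in at least 10% of its cells. A type also needed at least 1 in 3 of its listed markers. The 10 leading genes of a cluster then decided whether the name was kept. A cluster was left unnamed where these held more markers of another class, more genes of the glycogen list than own markers, or no own marker at a low UMI count. Where they held more markers of another type of the same class, only the class was kept. These rules and thresholds were chosen after the clusters were seen. The progenitor or astroglia class joins 7 clusters, and at day 10 most of its cells lie in 3 of them, whose proportions differ between libraries. A further one of 677 cells, with a median of 1993 UMIs and GSTA4L as its first leading gene, adds 28 and 123 brachial, 101 and 88 lumbar, and 38 and 79 polydactyl cells.

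Some clusters took no name, 5 of the 45. The first, with low UMI counts, held 3.804% of day 5 cells, 0.969% of day 7 cells and 0.115 to 0.372% of day 10 cells. The second, with leading markers of another class, held 3.665 and 2.166% of brachial, 3.441 and 3.028% of lumbar, and 2.105 and 3.046% of polydactyl cells. The third, with too few markers, held 0.718 and 1.968%, 2.944 and 1.56%, and 1.809 and 1.93%. The fourth, with leading markers of another class, held 3.891 and 3.773%, 2.156 and 1.904%, and 2.696 and 1.651%. The fifth, with leading genes of the glycogen list, is the lumbar-only cluster of the report.

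For the day 10 comparisons, counts were summed per library, since cells are not replicates. Genes were tested with edgeR 4.0.16 (TMM, filterByExpr, glmQLFit, glmQLFTest) on all 6 day 10 libraries by group, with Benjamini-Hochberg adjustment and a threshold of 0.05. Unless another tool is named, every adjusted p for a gene or class share comes from this test. Polydactyl libraries thus enter the spread of the lumbar comparison and the reverse, and both comparisons share the same brachial libraries. Named cell classes were tested where each library had at least 30 cells. Unnamed cells and progenitors or glia of unresolved type are mixtures and were not tested, although their smallest library held 186 and 45 cells. Class shares were tested with the same edgeR fit on cell counts, without TMM, and intervals on shares are exact binomial ones. Endothelium, floor plate, microglia, motor neuron-like, roof plate-like and newborn neuron classes and unresolved neurons fell below the minimum in some library and were not tested for genes. Motor neuron-like cells were tested for polydactyly alone, in 4 libraries with at least 20 cells each. The planned tests of axial level in motor neurons were not run, because the lumbar libraries held 1 and 10 such cells. The test of neurons against progenitors or astroglia, with library as a block, took the place of the planned one.

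Gene lists, 29 in all, and the comparisons, tests and alternatives of the main analysis were fixed before the data were examined. They were tested with camera of limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01 between genes and adjustment over the lists. Calls were repeated with an estimated correlation and with fry. Genes were named by a rule fixed beforehand: the 10 with a symbol and the smallest adjusted p in each direction in all cells and in motor neuron-like cells, up to 4 past the threshold per list (otherwise 1 or 2 as values), 5 per direction in other classes, and any HOX gene. For age the rule named the 10 largest rises and falls among genes with at least 50 CPM and steps in 1 direction, and 3 per list with at least 20 CPM.

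Age was described without a test from CPM with a pseudocount of 1 (alternative 5). Lists were placed among 10000 random lists matched on level within 100 genes on each side, over genes with at least 1 CPM. Alternatives for the tests were RLE scaling, no filter beyond 1 count, DESeq2 1.42.0, only the 2 groups compared, a replicate block, each library left out in turn, all barcodes, at least 2000 UMIs, no doublet removal, neural clusters alone and no haemoglobin or mitochondrial genes.

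Same-numbered libraries were checked for pairing. Their deviations from the group means correlated at 0.65 between brachial and lumbar, 0.628 between brachial and polydactyl, and 0.775 between lumbar and polydactyl. A first principal component with 49.7% of the variance separated number 1 (-33.1, -38.8 and -27.2) from number 2 (42.5, 25.5 and 31.1), and a second with 27.2% separated lumbar libraries. The pairing therefore comes from the data, not from the labels, and the fit without the block was kept as planned. Gene counts of same-group libraries differed more than counting allows, with a chi-square per degree of freedom of 137 over 13185 genes in brachial, 45.1 over 13191 in lumbar and 62.3 over 13186 in polydactyl cord.

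The tests were tested on simulated data with 200 changed genes, drawn only from genes above a minimum level. Recovery of genes at lower levels was not measured. In the lumbar comparison of all cells, edgeR found 26 of 50 genes changed 2-fold, 49 of 50 changed 4-fold, 49 of 50 changed 8-fold and 50 of 50 changed 16-fold, with 21 false calls among 13192 genes. DESeq2 found 39, 49, 49 and 50, with 69 false calls. In inhibitory neurons edgeR found 14, 44, 48 and 49 with 20 false calls among 10720 genes, and DESeq2 17, 43, 48 and 48 with 25. Camera called a planted list of 20 genes and did not call a random list of 20 genes, in all cells and in inhibitory neurons. Genes were simulated without correlation between them, so this does not measure false calls of lists whose members vary together. In the real data the estimated correlation reached 0.956, for floor plate markers in the lumbar comparison. The ranking of age lists, on values likewise drawn independently, put a planted list at percentile 100 and an unshifted one at 38.86.

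Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, scikit-learn 1.9.0, matplotlib 3.10.9 and R 4.3.3. Raw reads, splicing and sequence variants were not analysed here. Results of some genes that the naming rule selects are not reported here.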

Results

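Single-cell RNA libraries of embryonic chick spinal cord were compared across age, axial level and limb pattern. The samples were brachial cord at day 5 (1 library), day 7 (1 library) and day 10 (2 libraries), lumbar cord at day 10 (2 libraries), and day 10 brachial cord of embryos with induced polydactyly (2 libraries). Per the labels, extra digits were induced with beads soaked in retinoic acid, set into the anterior side of the early limb. Total depth was 75531837 UMIs at day 5 and 54031990 at day 7. At day 10 it was 37454459 and 63695014 UMIs in brachial libraries 1 and 2, 27712996 and 44128497 in lumbar, and 35754520 and 48814668 in polydactyl. After filtering, 34404 cells were used, 21968 of them from day 10. The labels do not say that replicates came from separate animals, so the p-values measure only the spread between these samples.

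At day 10 oligodendrocyte lineage cells and a progenitor or astroglia class were the largest named classes. Oligodendrocyte lineage cells made up 44.5 and 27.5% of brachial libraries 1 and 2, 27.7 and 25.7% of lumbar, and 30.5 and 28.2% of polydactyl cells. The progenitor or astroglia class made up 23.7 and 26.9%, 26.9 and 25.1%, and 22.9 and 23.9% in the same order. Inhibitory neurons made up 5.1 and 15.3% of brachial, 8.87 and 10.2% of lumbar, and 11.5 and 11% of polydactyl cells. Cells left without a name made up 16.9 and 18.1% of lumbar libraries, against 8.46 and 8.25% of brachial and 6.87 and 7.00% of polydactyl ones.

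**Figure D1:**
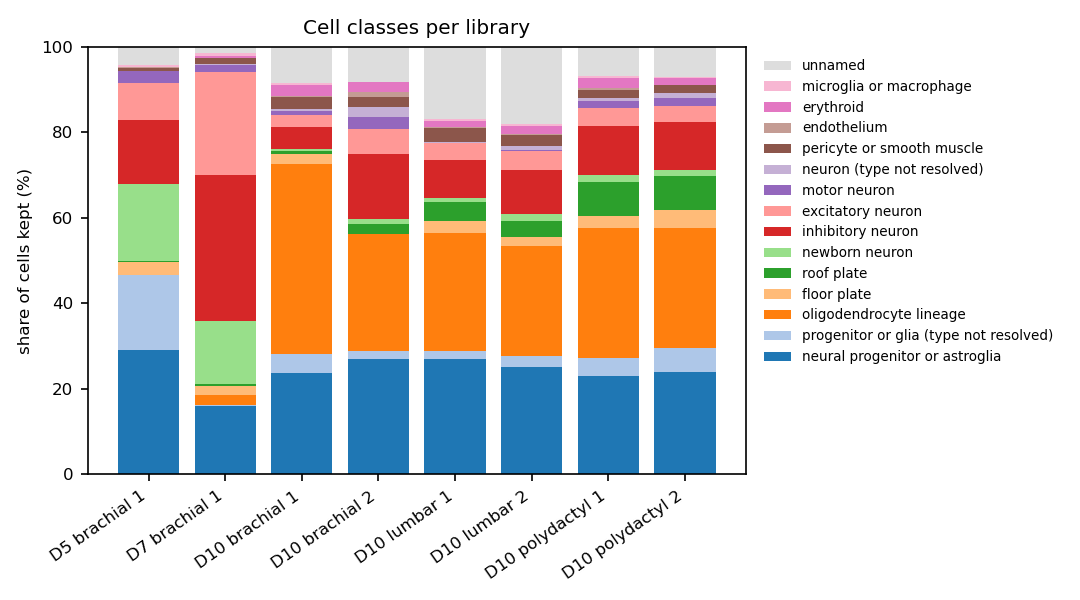
Share of cells in each class (stacked bars, vertical axis) for each of the 8 libraries (horizontal axis). Neurons of all types made up 74.9% of the day 7 library and 9.86 and 27.4% of day 10 brachial libraries 1 and 2.

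Which genes differ between lumbar and brachial cord at day 10? The posterior HOX genes separated the levels: HOXA11 stood at 0 in both brachial libraries and at 148.6 and 167.9 CPM in lumbar ones, at least 4840-fold (adjusted p = 0.00883). HOXD11 rose at least 4150-fold, to 122 and 147.7 CPM. HOXC10 rose from 1.52 and 0.576 to 248.4 and 260.1 CPM (log2 8.06 ± 0.465 s.e., adjusted p = 0.00907), and HOXD9 rose by log2 6.76 ± 0.533 (adjusted p = 0.0153). HOX transcription factors of higher paralogue number pattern the caudal body axis. HOXD10 rose at least 1760-fold, HOXD12 at least 1110-fold, HOXA10 at least 1060-fold, HOXC12 at least 429-fold and HOXC11 at least 130-fold. HOXA13 and HOXD13 rose from 1 and 2 pooled counts to 230 and 198, ratios of 330 (58.7 to 13100) and 142 (38.8 to 1180). These intervals, like all intervals on counts here, cover counting error only. Of the 14 measured HOX genes of paralogues 9 to 13, 11 rose and 3 did not pass; adjusted over the list alone, 12 rose. HOXA9 stood at 80.08 and 37.21 CPM in brachial and 297.3 and 302.5 CPM in lumbar cord (adjusted p = 0.126). It passed with the replicate block (adjusted p = 0.0184) and when adjusted over the list alone. HOXB9 (log2 -0.95 ± 0.442, adjusted p = 0.574) and HOXC9 (log2 0.17, adjusted p = 0.791) did not pass. Among paralogues 4 to 8 only HOXD8 rose, from 3.555 and 4.68 to 46.48 and 65.88 CPM (log2 3.83 ± 0.247, adjusted p = 0.0101). Red blood cells of the lumbar libraries, which should hold little HOX message of their own, carried HOXC10 at 8.04 and 10.7 CPM. Inhibitory neurons of those libraries carried it at 676.5 and 678.5 CPM.

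**Figure D2:**
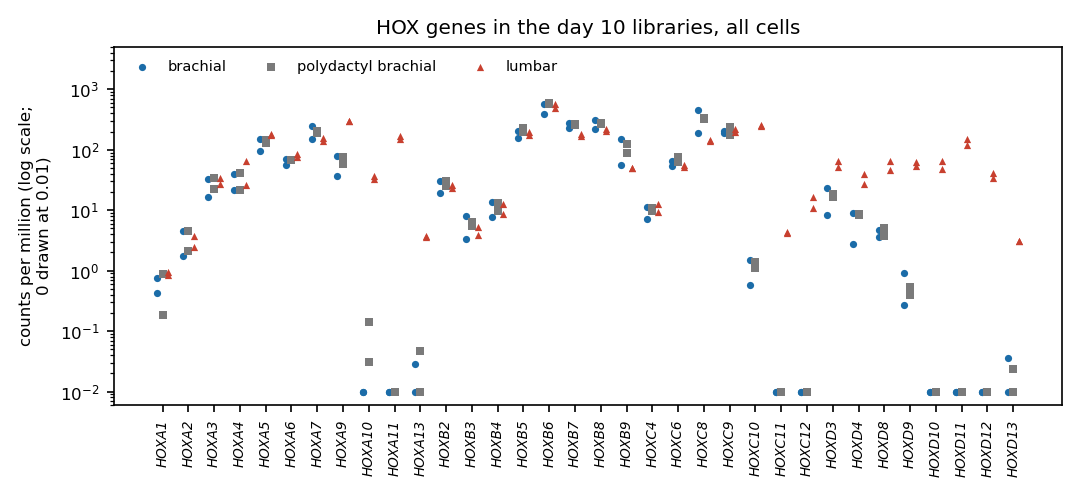
HOX gene levels in CPM (vertical axis, log scale, zeros at the bottom) in the 6 day 10 libraries (brachial, lumbar, polydactyl). HOXA11 was at 0 in both brachial libraries and at 148.6 and 167.9 CPM in the lumbar ones.

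Outside the HOX clusters, lumbar cord carried more message of a small set of glycogen and dorsal midline genes, and less of motor neuron genes. GBE1, the glycogen branching enzyme, rose from 126.9 and 101 to 779.1 and 962.2 CPM (log2 3.00 ± 0.182, adjusted p = 0.0101). GYG2, which primes glycogen synthesis, rose by log2 2.91 ± 0.227 (adjusted p = 0.0153) and PPP1R3B by log2 5.03 ± 0.423 (adjusted p = 0.0187). MSX2 rose from 4.903 and 9.936 to 102.6 and 130.2 CPM (log2 4.04 ± 0.36, adjusted p = 0.0222), and LMX1A, a roof plate transcription factor, rose by log2 3.18 ± 0.225 (adjusted p = 0.0121). Both also stood higher in polydactyl brachial cord against the same brachial libraries, though neither passed there. A higher level of these dorsal midline genes is thus not particular to lumbar cord. GSTA4L rose by log2 3.73 ± 0.182 (adjusted p = 0.00883), FAM222A by log2 2.21 ± 0.123 (adjusted p = 0.00883), ANGPTL1 by log2 2.25 ± 0.139 and HLX by log2 5.05 ± 0.326 (both adjusted p = 0.0101). Only 4 genes fell. UTS2B fell from 16.6 and 18.76 to 1.348 and 1.558 CPM (log2 -3.53 ± 0.196, adjusted p = 0.00883). ISL1, a motor neuron transcription factor, fell from 19.81 and 14.38 to 0.98 and 1.896 CPM (log2 -3.49 ± 0.353, adjusted p = 0.0322). CHAT, which makes acetylcholine, fell by log2 3.99 ± 0.411 (adjusted p = 0.0327) and LMCD1 by log2 2.28 ± 0.246 (adjusted p = 0.0395).

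In all, 51 of 13192 genes passed by edgeR's quasi-likelihood test, 47 higher and 4 lower in lumbar cord. Of these 12 were HOX genes, and 1224 genes lay at unadjusted p under 0.05. The replicate block gave 142 higher and 39 lower, with all 51 among them, and DESeq2 gave 241 and 104. By edgeR 0 genes passed without lumbar library 1 or without lumbar library 2, where 1 library stands for its group; the lowest adjusted p among named genes was then 0.0661 (GSTA4L) and 0.0956 (GBE1). The folds moved less. Over all libraries left out they ranged from log2 2.83 to 3.20 for GBE1, 3.52 to 3.97 for GSTA4L, 7.43 to 8.88 for HOXC10, -4.31 to -3.54 for CHAT and -3.59 to -3.46 for UTS2B. Without polydactyl library 1 or 2, which only inform the spread, 16 and 15 genes passed, and 19 passed when only the 4 compared libraries entered. Without brachial library 2, 34 passed. ISL1 did not pass without brachial library 1 (adjusted p = 0.058) or 2 (0.0528), nor did LMCD1 (0.058 and 0.0528), CXCL12 (0.0727 and 0.108) or GJA1 (0.0516 and 0.0908). PPP1R3B did not pass without brachial library 1 or 2 (0.058 and 0.0838), nor CHAT without brachial library 2 (0.0544). Without polydactyl library 1 or 2, ISL1 (adjusted p = 0.104 and 0.0985), CHAT (0.143 and 0.127), LMCD1 (0.0904 and 0.0966), MSX2 (0.0737 and 0.0646), LMX1A (0.0627 and 0.059), GYG2 (0.0572 and 0.0523), EFNB2 (0.169 and 0.141), CXCL12 (0.0854 and 0.072) and GJA1 (0.0904 and 0.0951) did not pass either. With neural clusters alone 8 genes passed.

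**Figure D3:**
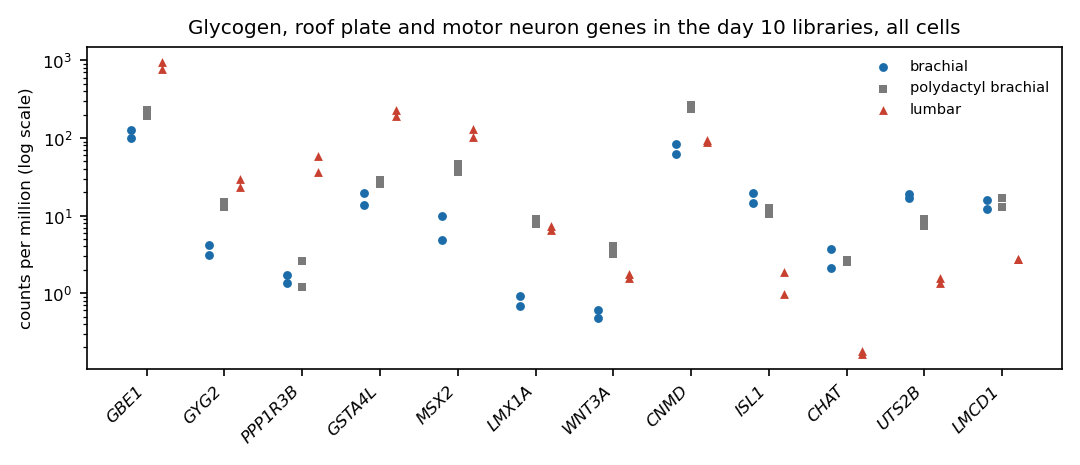
Levels of 12 named genes in CPM (vertical axis, log scale) in the brachial, lumbar and polydactyl libraries of day 10. MSX2 stood at 4.903 and 9.936 CPM in brachial, 102.6 and 130.2 in lumbar, and 45.53 and 36.32 in polydactyl libraries.

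A single lumbar cluster carried much of the glycogen signal. It held 8.04 and 11.5% of lumbar cells, 0 and 0.036% of brachial cells and 0% of polydactyl cells. It was left unnamed because its leading genes held more genes of the glycogen list than markers of its best type. Its cells carried GBE1 at 3318 CPM against 448.9 in the other lumbar cells, PPP1R3B at 284.8 against 6.944, ENO1 at 16370 against 1413 and MSX2 at 556 against 39.97. Without that cluster 11 genes passed. GBE1 then stood at log2 2.04 (adjusted p = 0.0509), GYG2 at 2.23 (0.0663), LMX1A at 2.33 (0.0663), GSTA4L at 1.45 (0.115), MSX2 at 2.47 (0.156) and PPP1R3B at 2.19 (0.327), none of them past the threshold. ISL1 (adjusted p = 0.0916), CHAT (0.0887) and LMCD1 (0.0923) did not pass there either, at log2 -3.30, -3.79 and -2.15. Without motor neuron-like cells UTS2B stood at log2 -0.57 (adjusted p = 0.821), ISL1 at -1.14 (0.536), CHAT at -1.60 (0.67) and LMCD1 at 0.12 (0.942). ISL1 and CHAT are among the markers that name those cells, so their smaller falls follow in part by construction.

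Do fixed gene lists shift in lumbar cord? HOX paralogues 9 to 13 had a median log2 change of 9.24, or 8.05 with genes absent from brachial cord at their bound, and were called up by camera (adjusted p = 1.69e-65), though adjusted p = 0.0657 with an estimated correlation. Glycogen metabolism (18 genes, median 0.23) was called up (adjusted p = 6.48e-09), with GBE1, GYG2 and PPP1R3B higher, 0 lower and 15 not past (adjusted p = 0.183 with an estimated correlation). Adjusted over the list alone, 5 glycogen genes rose. Roof plate markers (11 genes, median 0.90) were called up (adjusted p = 3.83e-09), with 2 higher, 0 lower and 9 not past (adjusted p = 0.183 with an estimated correlation). Adjusted over the list alone, 6 roof plate markers rose and 1 fell. Roof plate-like cells made up 4.48 and 3.65% of lumbar libraries against 0.831 and 2.31% of brachial ones (log2 1.36, adjusted p = 0.414). Polydactyl cord, set against the same brachial libraries, had a roof plate median of 1.20 and shares of 7.98 and 7.93%. The roof plate shift is thus not particular to lumbar cord. Cholinergic genes (11 genes, median -0.68) were called down (adjusted p = 8.79e-08), with CHAT lower and 10 not past; adjusted over the list alone, 4 fell (adjusted p = 0.509 with an estimated correlation). Motor column and pool genes (24 genes, median -0.18) were called down (adjusted p = 0.000134), with ISL1 lower and 23 not past; adjusted over the list alone, 2 fell (adjusted p = 0.183 with an estimated correlation). BMP and WNT pathway genes (30 genes, median 0.14) were called up (adjusted p = 0.00652), with MSX2 higher and 29 not past; adjusted over the list alone, 6 rose and 2 fell. The BMP and WNT call had adjusted p = 0.509 with an estimated correlation, 0.0647 without brachial library 1, 0.0589 without lumbar library 2 and 0.139 without roof plate-like cells.

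HOX paralogues 4 to 8 (14 genes, median 0.18) were called up (adjusted p = 0.0431), with HOXD8 higher and 13 not past; adjusted over the list alone, 2 rose and 1 fell. That call had adjusted p = 0.759 with an estimated correlation, 0.0696 without the lumbar-only cluster, 0.114 without lumbar library 2, and 0.621 with the direction turned without brachial library 1. No single synapse gene passed, SYT4 standing at log2 -1.14 ± 0.169 (adjusted p = 0.0963, or 0.0474 with the replicate block). The synapse list (36 genes, median -0.40) was called down (adjusted p = 4.87e-06), with 1 lower when adjusted over the list alone. It had adjusted p = 0.679 with an estimated correlation, and 0.917 with the direction turned without brachial library 2. Ion channels of excitable cells (23 genes, none past, median -0.35) were called down (adjusted p = 0.000483). They had adjusted p = 0.757 with an estimated correlation, and 0.521 with the direction turned without brachial library 2. Dissociation stress genes (19 genes, none past, median 0.21) were called up (adjusted p = 0.000134; adjusted p = 0.509 with an estimated correlation), with EGR1 at log2 1.93 ± 0.406 (adjusted p = 0.217). Endothelium markers (11 genes, none past, median -0.70) were called down (adjusted p = 0.00602), although 1 rose when adjusted over the list alone. That call had adjusted p = 0.619 with an estimated correlation, 0.159 without brachial library 2 and 0.115 without lumbar library 2. Floor plate markers (8 genes, none past, median 0.99) were called up (adjusted p = 0.0129), with adjusted p = 0.757 with an estimated correlation, 0.0945 with the replicate block, and 0.934 with the direction turned without brachial library 2.

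The other 17 lists were not called, with adjusted p from 0.0731 to 0.924. Hedgehog genes had a median of 0.30, with SMO at log2 0.51 (adjusted p = 0.283), and were called up without brachial library 1 (adjusted p = 0.0355), without polydactyl library 1 (0.0435) and without the lumbar-only cluster (0.023). Fibroblast or meninges markers had a median of 0.06, 3 rising when adjusted over the list alone, and were called up with the replicate block (adjusted p = 0.0197), without brachial library 1 (0.00955), lumbar library 2 (0.0127), polydactyl library 1 (0.0318) or 2 (0.0371), without the lumbar-only cluster (0.0115) and without roof plate-like cells (0.00834). Neuronal differentiation genes had a median of -0.29 and were called without brachial library 1 (adjusted p = 4.7e-05), as were axon guidance genes (median -0.17, 0.00873) and microglia markers (median 0.32, 0.01). In the axon guidance list EFNB2 (log2 1.26 ± 0.141, adjusted p = 0.0425) and CXCL12 (log2 1.75 ± 0.196, adjusted p = 0.0425) rose; adjusted over the list alone, 2 rose and 2 fell. Without the lumbar-only cluster, EFNB2 stood at log2 0.72 (adjusted p = 0.477) and CXCL12 at 1.18 (0.227). Proliferation genes had a median of -0.03 and were called without brachial library 1 (adjusted p = 0.000551, direction turned), brachial library 2 (1.38e-08) or the lumbar-only cluster (0.00178). Oligodendrocyte genes had a median of -0.23 and were called without brachial library 1 (adjusted p = 0.0164, direction turned) or 2 (1.94e-08). Inhibitory neuron genes had a median of 0.03, a mean of -0.16 and a test direction of down. They were called without brachial library 1 (adjusted p = 0.0112) or 2 (0.00382, direction turned), as were excitatory neuron genes (median -0.28, 0.00339 and 0.00336, the latter turned).

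The remaining lists held few changes. Retinoic acid genes had a median of -0.00, a mean of 0.01 and a test direction of down, with CYP26B1 at log2 -1.37 ± 0.244 (adjusted p = 0.149); adjusted over the list alone, 1 fell. Astroglia genes (median -0.02) held 1 riser, GJA1 (log2 1.08 ± 0.111, adjusted p = 0.0327), which stood at log2 1.18 without the lumbar-only cluster (adjusted p = 0.053). Cartilage markers had a median of -0.03, a mean of 0.04 and a test direction of up, with 1 rising when adjusted over the list alone, and were called without the lumbar-only cluster (adjusted p = 0.0478). Schwann cell markers had a median of -0.21, with 1 falling when adjusted over the list alone. Medians were -0.31 for erythroid, -0.03 for pericyte, -0.34 for sensory ganglion and -0.25 for skeletal muscle markers.

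HOX genes of paralogues 9 to 13 rose in lumbar cells in 4 of 6 tested cell classes, but 0 HOX genes passed in pericytes (4 of paralogues 9 to 13 and 9 of 4 to 8 measured, lowest adjusted p = 0.105) and in red blood cells (only HOXC8 measured, adjusted p = 0.999). In inhibitory neurons HOXC10 rose from 1.747 and 0.222 to 676.5 and 678.5 CPM (log2 10.41 ± 0.445, adjusted p = 0.000868), HOXD11 at least 720-fold and HOXA11 at least 289-fold, while HOXA7 fell by log2 1.33 ± 0.126 (adjusted p = 0.0303). HOXA7 did not pass without brachial library 2, lumbar library 1 or 2, or polydactyl library 1 or 2. Its fold stayed at log2 -1.38 to -1.26 over all libraries left out. At Leiden resolution 2 neither HOXA7 (adjusted p = 0.239) nor HOXC10 (0.227) passed in inhibitory neurons. Inhibitory HOXD11 and HOXA11 did not pass without lumbar library 1 (0.111 and 0.192) or 2 (0.121 and 0.169). In excitatory neurons HOXD11 rose at least 426-fold and HOXA11 at least 145-fold, and HOXC8 fell from 884.7 and 1109 to 247.1 and 272.2 CPM (log2 -1.89 ± 0.148, adjusted p = 0.00467). Excitatory HOXC10 rose by log2 6.11 ± 0.635 (adjusted p = 0.0195). It did not pass without brachial library 2 (0.11), lumbar library 1 (0.0979) or 2 (0.0986), nor by DESeq2 (0.553), but the fold stayed at log2 4.87 to 7.30 over all libraries left out. Without lumbar library 2, excitatory HOXA11 and HOXC8 did not pass (both 0.0872). In the oligodendrocyte lineage HOXC10 rose by log2 8.82 ± 0.258 (adjusted p = 0.000343) and HOXA11 at least 892-fold, though HOXA11 did not pass there without brachial library 1 (0.0749) or 2 (0.0734) or lumbar library 1 (0.289) or 2 (0.174). In progenitors or astroglia HOXD11 rose at least 775-fold and HOXD8 by log2 4.92 ± 0.307. GRIK3 rose there by log2 2.84 ± 0.242 (adjusted p = 0.0202), GBE1 by log2 1.87 ± 0.171 (adjusted p = 0.0248), and LUZP2 fell from 57.59 and 66.6 to 17.75 and 17.98 CPM (log2 -1.75 ± 0.182, adjusted p = 0.0376). LUZP2 did not pass without brachial library 1 or 2 or lumbar library 1 or 2. Its fold stayed at log2 -1.86 to -1.64 over all libraries left out. In pericytes COL3A1 rose by log2 1.64 ± 0.196 (adjusted p = 0.0208). It did not pass without lumbar library 1 (0.0528) or 2 (0.127), but the fold stayed at log2 1.54 to 1.72 over all libraries left out.

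Counts higher and lower in lumbar cells were 5 and 1 of 9226 genes in excitatory neurons, 5 and 1 of 10720 in inhibitory neurons, and 16 and 3 of 11246 in progenitors or astroglia. They were 4 and 0 of 11305 in the oligodendrocyte lineage and 1 and 0 of 6689 in pericytes. In red blood cells 0 of 2548 genes passed by edgeR and 0 by DESeq2, with 33 at unadjusted p under 0.05. With the replicate block excitatory neurons gave 69 genes, inhibitory neurons 17, progenitors or astroglia 365, the oligodendrocyte lineage 12 and pericytes 27. Without lumbar library 1 or 2, progenitors or astroglia and pericytes gave 0 and inhibitory neurons 1. Excitatory neurons gave 1 without lumbar library 2 and 3 without brachial library 2, but 9 without lumbar library 1. The oligodendrocyte lineage gave 1 without any one brachial or lumbar library, and progenitors or astroglia gave 8 without brachial library 1 and 8 without 2. Inhibitory neurons gave 15 and 17 without brachial library 1 and 2, pericytes 8 without brachial library 2 and 4 without either polydactyl library, and red blood cells 1 without lumbar library 2.

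Does axial level act differently on neurons and on progenitors or astroglia? In this test, chosen after the class results were seen, 6 of 11996 genes passed, 1 with a higher and 5 with a lower response in neurons, and 577 lay at unadjusted p under 0.05. HOXD8 went from 6.92 and 9.27 to 18.6 and 23.2 CPM in neurons, and from 0.86 and 1.5 to 31.1 and 42.4 CPM in progenitors or astroglia (log2 -3.55 ± 0.306, adjusted p = 0.0277). GRIK3, a glutamate receptor subunit, went from 366.4 and 344.9 to 430.4 and 395 CPM in neurons and from 45.7 and 33.69 to 284.5 and 260.4 CPM in progenitors or astroglia (log2 -2.59 ± 0.237, adjusted p = 0.0277). HOXA7 (log2 -1.36 ± 0.144), HOXD4 (-2.81 ± 0.299) and HOXD3 (-2.68 ± 0.285) also responded lower in neurons, each at adjusted p = 0.0282. LRRFIP1 had the opposite difference (1.18 ± 0.123, adjusted p = 0.0282), but it did not rise in neurons. It went from 155.6 and 181.4 to 57.08 and 77.11 CPM in progenitors or astroglia. In neurons it went from 68.47 and 70.31 to 56.43 and 68.4 CPM. Without lumbar library 1 or 2, 0 and 1 genes passed, and without brachial library 1 or 2, 51 and 48.

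Do the cell class shares differ between levels? None of the 14 classes tested passed. Cells without a name were not among them. These include the lumbar-only cluster, with 0 and 0.036% of brachial and 8.04 and 11.5% of lumbar cells. Motor neuron-like cells made up 1.10% (0.735 to 1.57) and 2.78% (2.36 to 3.25) of brachial libraries, against 0.041% (0.001 to 0.231) and 0.229% (0.11 to 0.421) of lumbar ones. That is log2 -3.71, lower in both lumbar libraries than in both brachial ones (adjusted p = 0.13; 0.0701 with the replicate block). It was the only class at unadjusted p under 0.05. Over all libraries left out, the motor neuron-like share moved by log2 -5.44 to -2.74 and the roof plate-like share by 0.798 to 2.27. With 1 brachial library left out, the spread came from the lumbar and polydactyl libraries alone, so calls of those fits are not given. The inhibitory neuron share moved by log2 -0.10, by -0.68 without brachial library 1 and by 0.91 without brachial library 2.

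Does induced polydactyly change brachial cord at day 10? The dorsal midline genes LMX1A, WNT3A and MSX2 stood higher in both polydactyl libraries, though no single gene passed. LMX1A stood at 0.688 and 0.918 CPM in brachial and 8.997 and 7.862 CPM in polydactyl cord (log2 3.37 ± 0.226, adjusted p = 0.124). WNT3A stood at 0.602 and 0.486 against 4.103 and 3.182 CPM (log2 2.74 ± 0.301, adjusted p = 0.193), and MSX2 at log2 2.46 ± 0.338 (adjusted p = 0.324). CNMD stood at 84.12 and 61.33 against 266.3 and 235.6 CPM (log2 1.78 ± 0.191, adjusted p = 0.193), COL1A2 at log2 1.94 ± 0.217 (adjusted p = 0.193) and GYG2 at log2 1.93 ± 0.22 (adjusted p = 0.193). By edgeR 0 of 13192 genes passed, with 538 at unadjusted p under 0.05 and 96 by DESeq2. With the replicate block 7 genes passed, all higher: LMX1A, CNMD, COL1A2, CAB39L, ADGRD2, KLHDC8B and OLFML3. None of 34 HOX genes passed (lowest adjusted p = 0.901), and HOXA11, HOXC11, HOXC12, HOXD10, HOXD11 and HOXD12 were at 0 in all 4 brachial libraries with and without polydactyly. HOXB6 stood at log2 0.29, HOXC6 at log2 0.23, and HOXA10 at 7 pooled counts against 0, at least 2.79-fold.

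Roof plate markers (11 genes, median log2 1.20) were called up in polydactyl cord (adjusted p = 4.31e-25; adjusted p = 0.161 with an estimated correlation). Floor plate markers (8 genes, median 1.51) were called up as well (adjusted p = 1.46e-08; adjusted p = 0.512 with an estimated correlation). Adjusted over the list alone, 6 roof plate markers and 1 floor plate marker rose. Hedgehog pathway genes (13 genes, median 0.34) were called up (adjusted p = 5.28e-07; adjusted p = 0.161 with an estimated correlation), with CDON at log2 0.65 ± 0.147 (adjusted p = 0.726). BMP and WNT pathway genes (30 genes, median 0.14) were called up (adjusted p = 2.01e-08; adjusted p = 0.359 with an estimated correlation; 0.288 without roof plate-like cells), and 7 rose when adjusted over the list alone. Dissociation stress genes (19 genes, median 0.28) were called up (adjusted p = 2.01e-08; adjusted p = 0.359 with an estimated correlation), 4 rising when adjusted over the list alone, with FOS at log2 1.12 ± 0.259 (adjusted p = 0.726). Axon guidance genes (42 genes, median 0.03) were called up (adjusted p = 0.00301; adjusted p = 0.701 with an estimated correlation), but not without brachial library 1 (0.903, direction turned). Adjusted over the list alone, 5 of them rose, and SLIT2 stood at log2 1.07 ± 0.144 (adjusted p = 0.32).

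Proliferation genes (33 genes, median -0.24) were called down (adjusted p = 1.24e-07; adjusted p = 0.701 with an estimated correlation), with AURKA at log2 -0.47, but not without brachial library 1 (0.519, direction turned). Pericyte markers (7 genes, median -0.45) were called down (adjusted p = 0.00222; adjusted p = 0.436 with an estimated correlation), with PDGFRB at log2 -0.45, but not without brachial library 1 (0.3). Glycogen genes (18 genes, median 0.08) were called up (adjusted p = 0.012; adjusted p = 0.626 with an estimated correlation), 2 rising when adjusted over the list alone. That call was absent without brachial library 2 (0.233), polydactyl library 1 (0.0781) or roof plate-like cells (0.237). Inhibitory neuron genes (15 genes, median 0.21) were called up (adjusted p = 0.043; adjusted p = 0.701 with an estimated correlation), but not without brachial library 1 (0.321, direction turned) or polydactyl library 2 (0.251). No member of these 10 called lists passed over all genes.

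The other 19 lists were not called, with adjusted p from 0.0585 to 0.977 and no member past. HOX paralogues 4 to 8 had a median of 0.11 and were called up without brachial library 2 (adjusted p = 4.89e-08). Cholinergic genes had a median of -0.19 and were called without brachial library 1 (adjusted p = 0.000466) or 2 (0.00814, direction turned). Synapse genes (median -0.08) were called without brachial library 1 (adjusted p = 2.42e-10) or 2 (8.99e-07, direction turned), as were ion channels (median -0.09, 3.05e-07 and 6.27e-06, the latter turned). Oligodendrocyte genes had a median of -0.12 and were called without brachial library 1 (1.41e-05, direction turned) or 2 (9.81e-07). Excitatory neuron genes had a median of -0.01, a test direction of up, and were called without brachial library 1 (0.0224, direction turned) or 2 (6.27e-06). Neuronal differentiation genes had a median of -0.01, a mean of 0.06, and were called without brachial library 1 (0.0224, direction turned), brachial library 2 (0.000117) or roof plate-like cells (0.0488). Fibroblast markers had a median of 0.02 and were called up with the replicate block (adjusted p = 0.00477), without brachial library 1 (0.00839) and without polydactyl library 2 (0.0379), and 1 rose when adjusted over the list alone.

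Endothelium markers had a median of -0.46 and were called without brachial library 1 (0.0224), polydactyl library 1 (1.58e-08) or roof plate-like cells (0.00526); adjusted over the list alone, 1 rose and 1 fell. Erythroid markers (median -0.21) were called without polydactyl library 1 (adjusted p = 3.66e-09) and microglia markers (median 0.09) without brachial library 1 (0.0152). Retinoic acid genes had a median of -0.05, a mean of 0.10 and a test direction of up, with STRA6 at log2 0.86 ± 0.206 (adjusted p = 0.726). Motor column genes had a median of -0.10 and a mean of 0.02, with a test direction of down. Schwann cell markers had a median of 0.16 and a test direction of down, and cartilage markers a median of -0.33. Adjusted over the list alone, 1 Schwann marker and 1 cartilage marker fell and 1 cartilage marker rose. HOX paralogues 9 to 13 had a median of 0 (0.26 at the bound), a mean of 0.40 and a test direction of up. Medians were -0.05 for astroglia, -0.11 for sensory ganglion and 0.09 for skeletal muscle lists.

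Roof plate-like cells made up 0.831% (0.522 to 1.26) and 2.31% (1.93 to 2.74) of brachial libraries and 7.98% (6.98 to 9.06) and 7.93% (7.14 to 8.78) of polydactyl ones. That is log2 2.32, higher in both polydactyl libraries (adjusted p = 0.157), and 0 of 14 classes passed. Over all libraries left out, the roof plate-like share moved by log2 1.78 to 3.25. Floor plate-like cells made up 2.34 and 0% of brachial libraries 1 and 2 and 2.84 and 4.12% of polydactyl ones (4 cells in brachial library 2 at Leiden resolution 2). The floor plate list was called up with either brachial library left out. The share of floor plate-like cells moved by log2 1.61 (adjusted p = 0.699) and by 0.597 without brachial library 2. Without brachial library 1 the only control held 0 such cells, so no ratio is given. Motor neuron-like cells made up 1.59% (1.15 to 2.13) and 1.95% (1.56 to 2.41) of polydactyl libraries, within the brachial range. In motor neuron-like cells 0 of 8652 genes passed by edgeR, with 232 at unadjusted p under 0.05 and 1 by DESeq2. FOS stood lowest, at log2 1.80 ± 0.219 (adjusted p = 0.605). Without brachial library 1 or 2, 11 and 18 genes passed there, and 4 with the replicate block. Of 21 lists in those cells, astroglia genes (median 0.36, adjusted p = 0.000125) and stress genes (0.08, 0.02) were called up and oligodendrocyte genes (-0.52, 0.0164) down. Each had adjusted p = 0.795 with an estimated correlation. By edgeR 0 genes passed in each of the 6 tested classes, with 164 at unadjusted p under 0.05 in excitatory neurons, 108 in inhibitory neurons, 237 in progenitors or astroglia, 128 in the oligodendrocyte lineage, 154 in pericytes and 53 in red blood cells. DESeq2 gave 1 gene, in progenitors or astroglia, and 0 in the others. The replicate block gave 1 in excitatory neurons (CCK), 3 in inhibitory neurons, 1 in progenitors or astroglia (HBM) and 4 in pericytes. Inhibitory neurons gave 9 without brachial library 1, pericytes 6 without brachial library 2 and red blood cells 2 without polydactyl library 1.

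How does brachial cord change from day 5 to day 10? Myelin and astroglial genes climbed from near absence, with day 5 and day 7 measured in 1 library each and without a test. BCAS1 stood at 1.605 CPM at day 5, 17.5 at day 7, and 1392 and 624.4 in day 10 libraries 1 and 2 (log2 8.60 against day 5). SOX10, which drives the oligodendrocyte lineage, stood at 0.087, 4.707, 162 and 70.74 CPM in the same order (log2 6.76). MBP stood 6.20 and PMP2 6.70 log2 units above day 5. The water channel AQP4 stood at 0.434, 3.272, 93.98 and 119.3 CPM (log2 6.23), the matrix gene TNC at 1.865, 36.6, 755.5 and 665.2 CPM (log2 7.96), and BCAN at log2 6.30. Globin message switched: HBBA stood at 16.23, 2170, 6692 and 4598 CPM (log2 8.36) and HBE1 at log2 6.54, while embryonic HBZ stood at 909.6, 231.9, 11.7 and 35.87 CPM (log2 -5.20). Early neuron genes stood lower at day 10, LHX1 at 406.7, 287.4, 16.28 and 70.98 CPM (log2 -3.19), PTF1A at log2 -3.83, TFAP2B at -3.41 and OTP at -3.15. HOXD4 stood at 106.8, 60.39, 2.752 and 9.108 CPM (log2 -3.96) and HOXD3 at log2 -3.26. Both depend on cell class. HOXD4 stood at 16.02 and 25.25 CPM in inhibitory and excitatory neurons of day 10 libraries 1 and 2. In their progenitors or astroglia it stood at 0.716 and 1.417 CPM. HOXD3 likewise stood at 48.44 and 71.11 against 1.719 and 2.913 CPM. Of 4242 genes at 50 CPM or more, 747 were higher and 411 lower at both steps, or 508 and 761 with TMM scaling. The median over all genes was 0.155 log2 units at day 10 by CPM and -0.003 by TMM. Age is confounded with library date and pipeline version in the file headers. Of the day 10 libraries, library 1 lacked W-linked message as days 5 and 7 did, and library 2 carried it. Class shares also change with age (below), so levels over all cells do not separate regulation from cell composition.

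**Figure D4:**
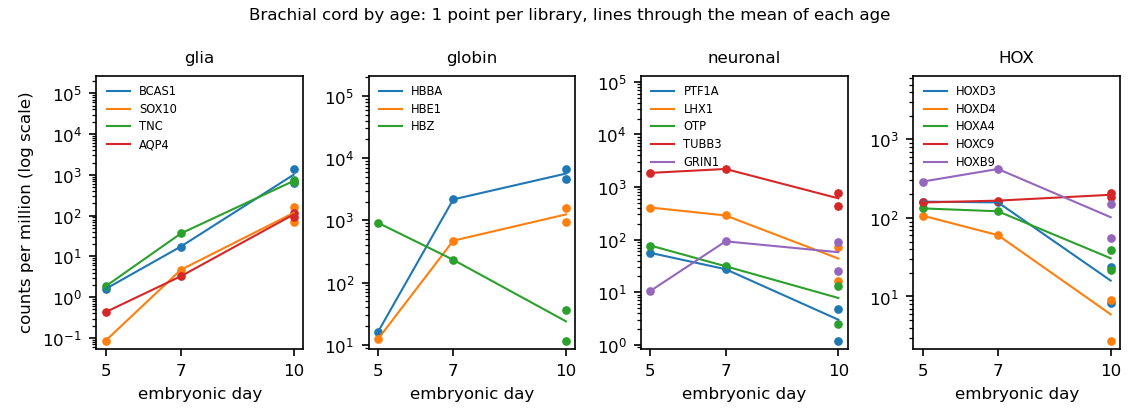
Levels in CPM (vertical axis, log scale) of glial, globin, neuronal and HOX genes in brachial cord at days 5, 7 and 10 (horizontal axis), with points for libraries and lines through means. HBBA went from 16.23 to 2170 CPM between days 5 and 7 while HBZ went from 909.6 to 231.9 CPM.

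Neurons made up 44.5% (43.2 to 45.8) of cells at day 5, 74.9% (73.9 to 75.9) at day 7, and 9.86 and 27.4% in day 10 libraries 1 and 2. Progenitors and glia made up 49.8% (48.4 to 51.1), 18.9% (18 to 19.8), and 31.2 and 31.0%, without the oligodendrocyte lineage. The oligodendrocyte lineage went from 0.018% (0 to 0.101) at day 5 to 2.29% (1.95 to 2.67) at day 7 and 44.5 and 27.5% at day 10. Inhibitory neurons made up 15% (14.1 to 16) at day 5 and 34.3% (33.2 to 35.4) at day 7, and excitatory neurons 8.51% (7.79 to 9.28) and 24.0% (23.0 to 25.1). Motor neuron-like cells made up 2.83% (2.41 to 3.3) at day 5 and 1.69% (1.40 to 2.02) at day 7.

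Which gene lists move most with age? The medians are over all cells, so they also follow the changing class shares. Oligodendrocyte genes had the largest median at day 10, log2 5.65, and stood at 1.69 at day 7 against day 5, above all random lists of matched level. Astroglia genes stood at 2.43 at day 10 and 1.10 at day 7, and erythroid markers at 3.01 and 1.96, also above all random lists. Schwann markers stood at 1.71 (percentile 99.99), endothelium at 1.03 (99.79), sensory ganglion at 1.53 (99.24), pericyte at 1.17 (99.15), glycogen genes at 0.48 (96.06) and fibroblast markers at 0.83 (95.53). With a pseudocount of 5 CPM Schwann markers stood at 0.59 and endothelium at 0.38, and with neural clusters alone endothelium stood at 0.19. Day 10 libraries 1 and 2 stood at 1.95 and 1.14 for Schwann and 1.14 and 0.51 for fibroblast markers. HOX paralogues 4 to 8 stood at -1.24, neuronal differentiation genes at -1.17, floor plate markers at -1.13, roof plate markers at -0.63, retinoic acid genes at -0.52 and axon guidance genes at -0.34, each below all random lists. Neuronal differentiation and axon guidance genes stood at 0.48 (98.99) and 0.61 (99.99) at day 7, above day 5. Day 10 libraries 1 and 2 stood at -0.84 and -0.26 for roof plate markers, -0.70 and -1.55 for floor plate markers, -0.48 and -0.08 for axon guidance genes and -1.75 and -0.80 for neuronal differentiation genes. Hedgehog genes stood at -0.41 (percentile 0.04), microglia markers at -0.49 (0.16), excitatory neuron genes at -0.25 (0.33; -0.91 and -0.05 in libraries 1 and 2) and HOX paralogues 9 to 13, with 4 measured, at -0.59 (1.63). Synapse genes rose first, to a median of 1.10 at day 7, with GRIN1 going from 10.58 to 92.68 CPM, and stood at 0.28 at day 10 (91.74). Ion channels stood at 1.28 at day 7 and 0.41 at day 10 (93.95), and proliferation genes at -1.18 and 0.23 (95.85). Motor column genes stood at 0.33 (92.15), cartilage markers at 0.49 (81.2), stress genes at 0.05 (53.08) and muscle markers at 0.01 (20.24). The sign turned between day 10 libraries 1 and 2 for synapse genes (-0.25 and 0.53), ion channels (-0.08 and 0.80), cholinergic genes (-0.27 and 0.33, median 0.12, percentile 28.74) and inhibitory neuron genes (-0.92 and 0.03, median -0.42, percentile 0.05). It also turned for proliferation genes (0.45 and -0.04) and BMP and WNT genes (-0.28 and 0.06, median -0.06, percentile 1.78), stress genes (-0.01 and 0.16) and skeletal muscle markers (-0.09 and 0.11). HOX paralogues 9 to 13 stood at -0.77 with TMM scaling, and microglia markers at 0.05 with neural clusters alone. With a pseudocount of 5 CPM microglia markers stood at -0.15 and excitatory neuron genes at -0.06.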

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

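The tests of 1 cluster as the source of lumbar genes, of doublets or depth in it, of a dissection with less ventral cord, of a dissection with more dorsal midline, of roof plate genes within roof plate-like cells, and of neurons against progenitors or astroglia were chosen only after the results were seen, as were the repeats with the lumbar-only cluster, roof plate-like cells or motor neuron-like cells removed.

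The lumbar against brachial change of 6 genes stood out because it differed between neurons and progenitors or astroglia past the threshold. The difference in log2 change, neurons minus progenitors or astroglia, was -3.55 for HOXD8, -2.59 for GRIK3, -1.36 for HOXA7, -2.81 for HOXD4, -2.68 for HOXD3 and 1.18 for LRRFIP1. For HOXD8, GRIK3, HOXD4 and HOXD3 the lumbar level was higher in both cell groups, and more so in progenitors or astroglia. HOXA7 was lower in lumbar neurons and nearly level in progenitors or astroglia. LRRFIP1 was lower in lumbar progenitors or astroglia and moved less in neurons.

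Genes outside the HOX clusters rose in lumbar cord, and a single cluster held by lumbar libraries may carry them. Over 35 such genes the median log2 ratio was 2.13 with the cluster and 1.04 without it (1.00 and 1.07 in lumbar libraries 1 and 2). These genes were chosen for passing as higher in the same libraries with the cluster in. Some fall and some remainder above 0 thus follow in part from the choice. GBE1 also rose in progenitors or astroglia, which leave the cluster out. That class holds a low-UMI cluster led by GSTA4L, as the lumbar-only cluster is, with 101 and 88 lumbar cells. It was not tested without those cells, so the part of the lumbar-only cluster stays open. Free RNA that reached every droplet alike is argued against for most of the summed excess of these genes. Without the cluster 30.5% of it was left (38.2 and 24.3%). Whether that part is message leaked from the cluster's cells is not decided, since removing the cluster leaves leaked message in place. Doublets are argued against by 3.99% of its barcodes left out as doublets against 4.03% elsewhere, though its median of 14205 UMIs is 1.66 times the 8543 of other lumbar cells. Cells of 4 neighbouring tissues are argued against by a highest median marker fold of 0.629, for skeletal muscle, although 3 of 10 fibroblast or meninges markers stood over 2-fold higher (COL1A2 at 50.9 against 24.88 CPM) and 7 under 0.5-fold, and the axial level itself stays open.

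Motor neuron-like cells were scarce in both lumbar libraries, which could come from the filters on barcodes, from dissection or from the tissue. Loss by the filters is argued against, since 9 motor neuron markers stood at a median log2 ratio of -2.31 over all deposited barcodes (-2.47 and -2.16) against -2.74 in the cells used. A dissection with less ventral cord cannot be told apart from a real shortfall. The lowest lumbar share of floor plate-like cells was 2.27% against 2.34% in brachial library 1, but brachial library 2 held none (upper limit 0.067%; 4 cells at Leiden resolution 2), so that share is a weak guide to ventral tissue. Lumbar libraries also had the highest median mitochondrial shares (8.7 and 8.01% against 4.85 and 5.74% in brachial) and stress genes called up (adjusted p = 0.509 with an estimated correlation), but stress genes were also called up in polydactyl cord (adjusted p = 0.359 with an estimated correlation), where these cells made up 1.59 and 1.95%, so a loss in poorer suspensions was not tested and stays open beside axial level.

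Roof plate genes stood higher in polydactyl cord, which could come from more roof plate-like cells or from more message in each. The median log2 ratio over 11 markers was 1.19 with those cells and 0.23 without them (0.23 and 0.28 in polydactyl libraries 1 and 2), but these markers name the cells, so that fall decides nothing. Nor does the median of 0.28 within those cells (0.37 and 0.07), since it rests on the same naming and on 2 subclusters in unlike proportions, with 7 and 110 against 15 and 21 brachial cells and 76 and 139 against 142 and 203 polydactyl cells. More such cells, more message in each, the operation and a dissection with more dorsal midline cannot be told apart. The lowest polydactyl share exceeded the highest brachial share by 5.62 percentage points, against a gap of 1.48 between the brachial libraries.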

How the results depend on the processing

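The alternatives with the lumbar-only cluster, roof plate-like cells or motor neuron-like cells removed, the test of neurons against progenitors or astroglia and the test in motor neuron-like cells were chosen after the data were seen; the others were chosen before. Of 3576 alternative values for single genes, lists and shares, 3199 gave the same call and size, 251 were weaker, 91 stronger, 19 reversed and 16 moved without a change of call. The cause of these shifts was not tested unless a sentence says so. Where a left-out library leaves a group with 1 library, that library was assumed to vary like the other groups. Excitatory neurons at Leiden resolution 2 were not run (15 cells in brachial library 1), nor were the planned motor neuron tests of axial level. At that resolution a cluster of 646 cells, 60 of them from brachial library 1, did not keep the excitatory name. Another of 958 cells, with leading genes like those of the largest inhibitory cluster at resolution 1, took no name. The neuron classes thus depend on the resolution. Other splits of the libraries were not counted, since each group has 2.

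By DESeq2 the lumbar comparison gave 345 genes instead of 51 and the polydactyl one 96 instead of 0. Lumbar calls by DESeq2 were 16 in inhibitory neurons (6 by edgeR), 97 in progenitors or astroglia (19), 18 in the oligodendrocyte lineage (4) and 2 in pericytes (1). Polydactyl calls by DESeq2 were 1 in progenitors or astroglia and 1 in motor neuron-like cells (0 by edgeR in both). In the simulated lumbar data DESeq2 made 69 false calls and edgeR 21.

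With the replicate block, the lumbar comparison gave 181 genes and the polydactyl one 7. Lumbar calls with the block were 69 in excitatory neurons, 17 in inhibitory neurons, 365 in progenitors or astroglia, 12 in the oligodendrocyte lineage and 27 in pericytes. Polydactyl calls with the block were 1 in excitatory neurons, 3 in inhibitory neurons, 1 in progenitors or astroglia, 4 in pericytes and 4 in motor neuron-like cells. Among lists, the block ended the lumbar floor plate call (adjusted p = 0.0945) and made calls of lumbar and polydactyl fibroblast markers (0.0197 and 0.00477). It changed no other list call and no share call.

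Without a filter beyond 1 count, red blood cells gave 3 lumbar and 6 polydactyl genes (0 and 0 with the filter), and excitatory neurons 80 lumbar and 6 polydactyl genes (6 and 0). Inhibitory neurons gave 14 lumbar genes (6), progenitors or astroglia 47 (19), pericytes 29 lumbar and 7 polydactyl genes (1 and 0), and motor neuron-like cells 25 (0). Without doublet removal pericytes gave 2 lumbar genes (1). With only the 2 groups compared, the lumbar comparison gave 19 genes. With neural clusters alone, which leave out the unnamed clusters, it gave 8, and without the lumbar-only cluster 11. LMCD1 turned from log2 -2.28 to 0.12 without motor neuron-like cells. RLE scaling gave 52 lumbar genes, all barcodes 43, at least 2000 UMIs 54, no doublet removal 48, and no haemoglobin or mitochondrial genes 51.

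With an estimated correlation, camera called 0 lumbar and 0 polydactyl lists, where the preset correlation of 0.01 called 12 and 10. Fry called 4 lumbar lists, HOX paralogues 9 to 13 (adjusted p = 0.000786), glycogen (0.0106), roof plate (0.0332) and skeletal muscle markers (0.0332), and 0 polydactyl lists.

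With 1 library left out, lumbar calls in all cells ranged from 0 to 52. They ranged from 0 to 1 in red blood cells, 1 to 9 in excitatory neurons, 1 to 17 in inhibitory neurons, 0 to 15 in progenitors or astroglia, 1 to 5 in the oligodendrocyte lineage and 0 to 8 in pericytes. Polydactyl calls ranged from 0 to 2 in red blood cells, 0 to 9 in inhibitory neurons, 0 to 6 in pericytes and 0 to 18 in motor neuron-like cells. The test of neurons against progenitors or astroglia ranged from 0 to 51 (6 with all libraries). The lumbar log2 change of the inhibitory share ranged from -0.677 to 0.908. Class share calls without a brachial library are not counted, since the spread then came from the other groups alone. The 52 genes in all cells came without brachial library 1 and the 0 without either lumbar library. The 9 in excitatory neurons came without lumbar library 1, the 15 in progenitors or astroglia and the 5 in the oligodendrocyte lineage without either polydactyl library. The report names the libraries behind the other ends.

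With 1 library left out, 10 to 19 lumbar lists and 10 to 16 polydactyl lists were called. Over these repeats the adjusted p of lumbar lists ranged from 3.61e-05 to 0.621 for HOX paralogues 4 to 8, 1.28e-16 to 0.917 for synapse genes, 4.96e-11 to 0.521 for ion channels and 1.55e-12 to 0.934 for floor plate markers. It ranged from 1.38e-08 to 0.786 for proliferation, 1.94e-08 to 0.603 for oligodendrocyte, 0.00382 to 0.981 for inhibitory neuron and 0.00336 to 0.812 for excitatory neuron genes. Directions turned without brachial library 1 for HOX paralogues 4 to 8 (0.621), proliferation (0.000551) and oligodendrocyte genes (0.0164). They turned without brachial library 2 for synapse genes (0.917), ion channels (0.521), floor plate markers (0.934), inhibitory (0.00382) and excitatory neuron genes (0.00336).

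For polydactyl lists the adjusted p ranged from 4.37e-07 to 0.903 for axon guidance, 0.000466 to 0.822 for cholinergic, 2.42e-10 to 0.825 for synapse and 3.05e-07 to 0.926 for ion channel genes. It ranged from 0.000117 to 0.908 for neuronal differentiation, 5.19e-23 to 0.519 for proliferation, 9.81e-07 to 0.933 for oligodendrocyte, 1.2e-08 to 0.321 for inhibitory neuron and 6.27e-06 to 0.795 for excitatory neuron genes. Directions turned without brachial library 1 for axon guidance (0.903), proliferation (0.519), inhibitory neuron (0.321), neuronal differentiation (0.0224), excitatory neuron (0.0224) and oligodendrocyte genes (1.41e-05). They turned without brachial library 2 for cholinergic (0.00814), synapse (8.99e-07) and ion channel genes (6.27e-06). Brachial libraries 1 and 2 differ in their share of neurons, 9.86 against 27.4%, so leaving out either moves the control level of neuronal and glial genes by construction.

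For age, a pseudocount of 5 CPM moved list medians at day 10 against day 5 toward 0 in most lists. They became -0.23 for retinoic acid genes (-0.52 before), 1.67 for astroglia genes (2.43), 4.80 for oligodendrocyte genes (5.65), 0.35 for glycogen genes (0.48) and -0.43 for floor plate markers (-1.13). They became 0.38 for endothelium, -0.15 for microglia, 0.80 for pericyte, 0.59 for Schwann, 1.19 for sensory ganglion and 0.15 for cartilage markers. HOX paralogues 9 to 13 went from -0.59 to -0.66.

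With TMM scaling, 761 genes fell at both steps instead of 411. List medians were -0.77 for HOX paralogues 9 to 13, -0.67 for retinoic acid, -0.57 for hedgehog, 0.31 for glycogen and -0.12 for stress genes (0.05 before), 0.92 for endothelium and 1.37 for sensory ganglion markers. With neural clusters alone they were -0.49 for HOX paralogues 9 to 13, -0.23 for proliferation (0.23 before) and 0.53 for glycogen genes. They were 1.77 for erythroid, 0.19 for endothelium, 0.05 for microglia (-0.49 before), 0.10 for pericyte and -0.24 for skeletal muscle markers (0.01 before). Leaving out red blood and vascular clusters lowers their own markers by construction.

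With day 10 brachial library 1 or 2 left out, age medians ranged from -0.51 to -0.42 for HOX paralogues 9 to 13, -0.45 to -0.33 for retinoic acid, -0.63 to -0.45 for hedgehog, -0.91 to -0.05 for excitatory neuron and 0.46 to 0.52 for glycogen genes. They ranged from 1.00 to 1.12 for endothelium and 1.14 to 1.95 for Schwann markers. A list's median over the mean of the libraries can lie outside this range, because members change order between libraries.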

Other observations

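The lumbar-only cluster pairs some glycogen and some dorsal genes with a mixed glial profile. Beside GBE1 and PPP1R3B, its cells carried GSTA4L at 1146 CPM against 44.38 in other lumbar cells, TNFRSF11B at 431.8 against 31.3, UGP2 at 302.7 against 56.36, and GYG2 at 82.74 against 16.74. Of 18 glycogen genes 5 stood over 2-fold higher, and the median fold was 1.15. ZIC1 stood at 501.3 against 185.6 CPM. Of 12 roof plate markers 5 stood over 2-fold higher and 4 under 0.5-fold, with a median fold of 0.734. OLIG2 stood at 5.873 against 1165 CPM and SLC1A3 at 401.1 against 1792, while FABP7 stood at 6138 against 7950, SOX2 at 259.2 against 449 and SOX9 at 255 against 328 CPM. Progenitor or astroglia markers had a median fold of 0.591, with 6 of 15 under 0.5-fold. HOXA11 stood at 472.4 against 103.6 CPM. Birds carry a glycogen body on the dorsal side of the lumbosacral cord, and these cells may belong to it. That is a hypothesis from the genes that set the cluster apart, and it was not tested here. Staining lumbosacral sections for glycogen together with GBE1 and PPP1R3B message would test it. A median of 1.04 log2 units of the lumbar change stayed without the cluster, over genes chosen for rising in these same libraries.

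The day 10 libraries with the same number deviated together, and a candidate explanation is the sex of the embryos. The tests were written before their values were seen. The W-linked genes SPIN1W and HNRNPKL stood at 0 to 0.547 CPM in number 1 libraries of day 10 and in the day 5 and day 7 libraries, and at 68.89 to 87.16 CPM in number 2 libraries. Birds with a W chromosome are female and carry a single Z. Over 347 Z genes the median log2 ratio of number 1 to number 2, less that of 7568 other genes, was 0.52 in brachial, 0.515 in lumbar and 0.512 in polydactyl cord (smallest 0.51), with 83.6, 85 and 88.2% of Z genes higher in number 1. In number 2 libraries, cells with no W-linked UMI were 1.192 (brachial), 1.079 (lumbar) and 1.162 (polydactyl) times as common as a single rate gives. These ratios stayed under the limit set beforehand for mixed sexes. They all lie above 1, and a minor share of cells without a W chromosome could give them, so mixing is not excluded. At most 34.15% of cells had no W-linked UMI, which argues against number 2 libraries made mostly of cells without a W chromosome. Z and W genes alone do not carry the shared deviations, whose lowest correlation without them was 0.57. The number may thus mark sex, and perhaps a date or a litter as well. If it does, sex was balanced across the day 10 groups. Day 5 and day 7 lack W-linked message, as number 1 does, and number 2 of day 10 brachial cord does not.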
